A study of Mus musculus with 4 samples.

How the data were processed

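Expression was measured by RNA-seq of sorted mouse mammary tumor cells, with libraries made by a low-input Clontech SMARTer mRNA kit, 2 libraries titled Lsd1 wild-type and 2 titled Lsd1 knockout, per the labels' protocols. The groups were taken from the sample titles, which the genotype labels also give; the tissue label of the 2 samples titled knockout reads Lsd1+/+ and was not used. The submitters' processing notes name the genome build mm9. The aligner, the quantification tool and the gene annotation are not given in the sources used here.

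The deposited table holds 1 value per gene and library in FPKM, that is, reads or fragments scaled by transcript length and by library total. The file's header names no unit, so it was read from the values. The columns have different totals, which TPM would not. Among genes below 0.1 FPKM, 55.0 to 63.4% stood in ratios of whole numbers up to 6 between libraries, within a tolerance of 0.2%, against 0.4 to 1.4% when the scale was moved off those steps. Values stepped with whole reads in this way, which gave a depth relative to the second library labelled knockout of 1.03 and 0.85 for wild-type and 0.93 for the other library labelled knockout. From 30 genes with a single transcript in GENCODE M21 the absolute depth was put at roughly 17000000 to 20600000 reads; this is an estimate, since the lengths the authors used are not known. Read counts were not rebuilt from it, and no count model was fitted.

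Of 24043 rows, 92 were spike-in sequences, all listed at 0, and were left out. A further 27 rows carry dates in place of gene symbols, as a spreadsheet writes them; they were tested but not named. Symbols were used as the file gives them. In the gene lists 1 symbol was matched through an older name (Emr1 for Adgre1) and 2 had no row (Ly6g and Hbb-b2). The annotation at hand is of another build than mm9, so no coordinates are given. A few rows were at 0 in a single library while at 20 FPKM or more in the other 3, between 0 and 4 per library.

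Genes with at least 1 FPKM in at least 2 libraries (11138) were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trended and robust prior, genotype as the sole term, and Benjamini-Hochberg adjustment at 0.05. Log2 differences are on this scale, which understates changes of genes near the pseudocount of 1. Values are given as mean ± SD of FPKM or as each library's FPKM in the order of replicates 1 and 2. With 2 libraries per group a permutation test has 3 splits and cannot reach 0.05, so the adjusted p-values rest on the model across genes. The fit was tested on simulated data over 11138 genes, comparing the libraries labelled knockout with wild-type, with the spread of each group's own pair. That spread was a running median over genes of similar mean level, so the shares called do not hold for genes that vary more. The fit called 2.3% of genes changed by a fold of 2, 43.7% at a fold of 4, 93% at 16 and 96.2% at 64. An average of 0.4 unchanged genes was called per run over 20 runs. Among unchanged genes 6.9% had an unadjusted p under 0.05. With the spread of the pair labelled knockout in both groups, 100% were called at each fold and 9.6 unchanged genes on average. Changed genes were drawn from those with a mean log2(FPKM + 1) above 3, with independent noise in each gene. The simulation thus holds no shifts shared by many genes, so its false calls do not bound those in these libraries.

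The 33 gene lists, 32 of which had the minimum of 3 tested members (the neuronal list did not), were tested against all other genes with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. With the preset correlation 14 lists passed, and with an estimated correlation 0 passed (lowest unadjusted p = 0.085, and 0 lists at an unadjusted p under 0.05). With 2 libraries per group that correlation was estimated from few residuals. Even the lymphocyte list, with 16 of 16 genes higher, had an unadjusted camera p of 0.17 there. Not passing with an estimated correlation thus does not show that a list is unchanged. The preset correlation in turn takes the genes of a list as nearly independent. Genes of 1 list could shift together between libraries: the luminal keratin median was 9.05 and 6.62 on the log2(FPKM + 1) scale in the wild-type libraries. Camera p-values at the preset correlation can therefore be too small. The fry test, which asks whether a list's genes move on balance in one direction, called 7. The lists, the tests and the rule for named genes were fixed before the data were examined. The rule named Kdm1a, the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose groups do not overlap and whose higher group mean is at least 5 FPKM, 7 focus genes, and up to 4 members of lowest p with a mean of at least 1 FPKM in each described list. Predicted genes, Rik and LOC entries and date rows were not named, and 2 of the 12 genes with the largest rise are not reported here. Some genes named besides these were chosen after their values were seen.

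The 2 libraries of each genotype were compared before they were averaged. For genes with an estimated 500 to 2000 reads the robust SD of the log2 difference was 0.141 in the pair labelled knockout and 0.499 in the wild-type pair, against 0.069 from counting alone. The pair labelled knockout thus differed by more than counting noise, which 2 preparations from 1 animal would also do. It was counted as 2 samples because the labels list 2, and the counts with the pair averaged are given as an alternative. The replicate numbers are not said to mark a shared litter, day or batch, and no batch is recorded. Alternatives were ordinary limma, median centring, quantile normalization, no filter and a filter at 5 FPKM, a pseudocount of 0.1, an adjusted p of 0.1, leaving out each library and the replicate number as a block. Rescaling each library to a common total, leaving out small RNA rows and averaging the pair labelled knockout were added after seeing the data. Figures were drawn with matplotlib 3.10.9.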

Results

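RNA was profiled in mammary tumor cells of MMTV-PyMT female mice, in which the polyoma virus middle T antigen is expressed in the mammary epithelium and drives tumors. The cells had been sorted for yellow fluorescent protein, a Rosa26 reporter that marks cells after Cre recombination, 2 to 3 months after an adenovirus carrying Cre under the Krt8 promoter was given into the ducts. There were 2 libraries titled Lsd1 wild-type and 2 titled Lsd1 knockout. The comparison asks how expression differs between tumor cells with and without LSD1, a histone lysine demethylase of the CoREST repressor complex that is encoded by Kdm1a. The deposited values were FPKM for 24043 rows, and they summed to 402436 and 449838 in the wild-type libraries and to 401786 and 402946 in the libraries labelled knockout. No read totals were given; the steps between the lowest values put the depth at roughly 20600000 and 17000000 reads in the wild-type libraries and 18600000 and 20000000 in the libraries labelled knockout. The number of rows at 1 FPKM or more was 10412 and 10927 in wild-type and 10320 and 10386 in the libraries labelled knockout. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these libraries. The wild-type pair was far less alike than the pair labelled knockout, with a Pearson correlation across genes of 0.85 against 0.98 on the log2(FPKM + 1) scale.

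Kdm1a, the gene targeted for deletion, was measured in all 4 libraries. Its level was 52.5 and 22.9 FPKM in the wild-type libraries and 20.2 and 22.8 FPKM in the libraries labelled knockout. The difference in mean log2(FPKM + 1) was -0.67 (SE 0.46, n = 2 and 2; limma, adjusted p = 0.34). The difference was therefore within the spread between replicates, and its size turned on 1 library. The difference was -0.09 without the first wild-type library and -1.25 without the second. With 1 wild-type library left, the fit holds no spread between wild-type libraries. Gene-level values do not separate deleted from retained exons, nor the RNA of recombined cells from that of other cells. This measurement therefore checks the labels only in part. The tissue label of both samples titled knockout also reads Lsd1+/+, while their genotype label reads knockout. These libraries are therefore called the libraries labelled knockout.

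**Figure D1:**
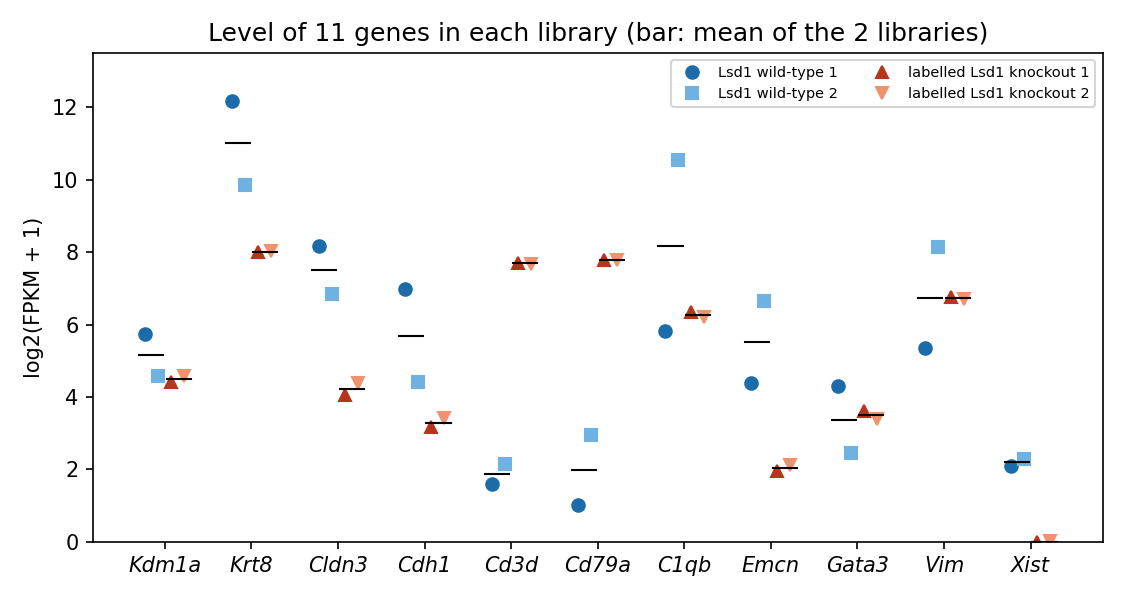
Level of 11 genes in each library, as log2(FPKM + 1); circles and squares are the 2 Lsd1 wild-type libraries, upward and downward triangles the 2 labelled knockout, and each short line is the mean of a pair. Kdm1a lies at nearly the same level in the second wild-type library (22.9 FPKM) and the libraries labelled knockout (20.2 and 22.8 FPKM), while Krt8 is lower and Cd3d and Cd79a are higher in both libraries labelled knockout than in either wild-type library.

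The named genes with large differences included lymphocyte transcripts, which were higher in the libraries labelled knockout, and secretoglobins, which were lower. Among named genes that rose were Cd3d, a chain of the T cell receptor complex (2.73 ± 1.01 FPKM in wild-type and 206 ± 3.38 in the libraries labelled knockout, SD, n = 2 each), and Cd79a, a chain of the B cell receptor complex (3.88 ± 4.01 and 220 ± 1.13 FPKM). Cd2, an adhesion receptor of T and NK cells, rose by 5.85 on the log2(FPKM + 1) scale (SE 0.93), Ms4a4b by 6.53 (SE 0.68) and Gimap3, a GTPase of lymphocytes, by 6.02 (SE 0.70). Among named genes that fell were the secretoglobins Scgb2b27 (116 ± 45.0 FPKM in wild-type and 1.09 ± 0.667 in the libraries labelled knockout) and Scgb1b27 (66.1 and 26.1 FPKM in wild-type, 0.62 FPKM and listed at 0 in the libraries labelled knockout), the secreted carbonic anhydrase Car6 (86.2 ± 76.6 and 2.01 ± 0.864 FPKM) and the water channel Aqp5 (181 ± 111 and 8.11 ± 0.175 FPKM).

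The other genes in that list fell by 3.52 to 3.73 on the log2(FPKM + 1) scale. Rbp7, a retinol-binding protein, changed by -3.73 (SE 0.18), Emid1 by -3.70 (SE 0.45), Serpina3h by -3.69 (SE 0.33) and Spint1, an inhibitor of epithelial serine proteases, by -3.61 (SE 0.53). Cox8b, a cytochrome oxidase subunit, changed by -3.55 (SE 0.29), the apolipoprotein gene Apoc1 by -3.54 (SE 0.57), the proton pump subunit Atp6v1b1 by -3.54 (SE 0.63) and the collagen gene Col9a1 by -3.52 (SE 0.62). A class I gene of the H2 family, H2-L, was at 0.000365 and 0.053 FPKM in wild-type and at 124 and 420 FPKM in the libraries labelled knockout; it shares sequence with other H2 genes, so its value is uncertain, and its call ended without the first (adjusted p = 0.13) or the second (adjusted p = 0.12) wild-type library. The small RNA rows Mir7058, Snord35b, Snord96a and Mir142b were listed at 0 in both wild-type libraries. In the libraries labelled knockout they were at 667 and 619 FPKM, 662 and 369 FPKM, 448 and 416 FPKM, and 74.9 and 86.9 FPKM. Such short annotations can lie inside longer host genes, so reads of the 2 cannot be told apart.

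In all, 1837 of 11138 tested genes passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 1059 of them higher and 778 lower in the libraries labelled knockout. Of these, 372 rose and 249 fell by at least 2 on the log2 scale. These counts rest on the close agreement of the pair labelled knockout: without either library labelled knockout 0 genes passed (1385 and 1346 at an unadjusted p under 0.05, respectively), and without the first or the second wild-type library 7719 and 7912 did. The call of each gene named above as risen or fallen was among those that ended. The call of Cd2 also ended with a pseudocount of 0.1 (limma, adjusted p = 0.0525), and those of Atp6v1b1 and Col9a1 when each library was rescaled to a common total (adjusted p = 0.0514 and 0.0506). With no filter on low values 2 genes passed, and none of the 1837 changed direction in any of the alternative settings run. These genes were picked for their difference in the same libraries, so their kept direction is little support for the calls.

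**Figure D2:**
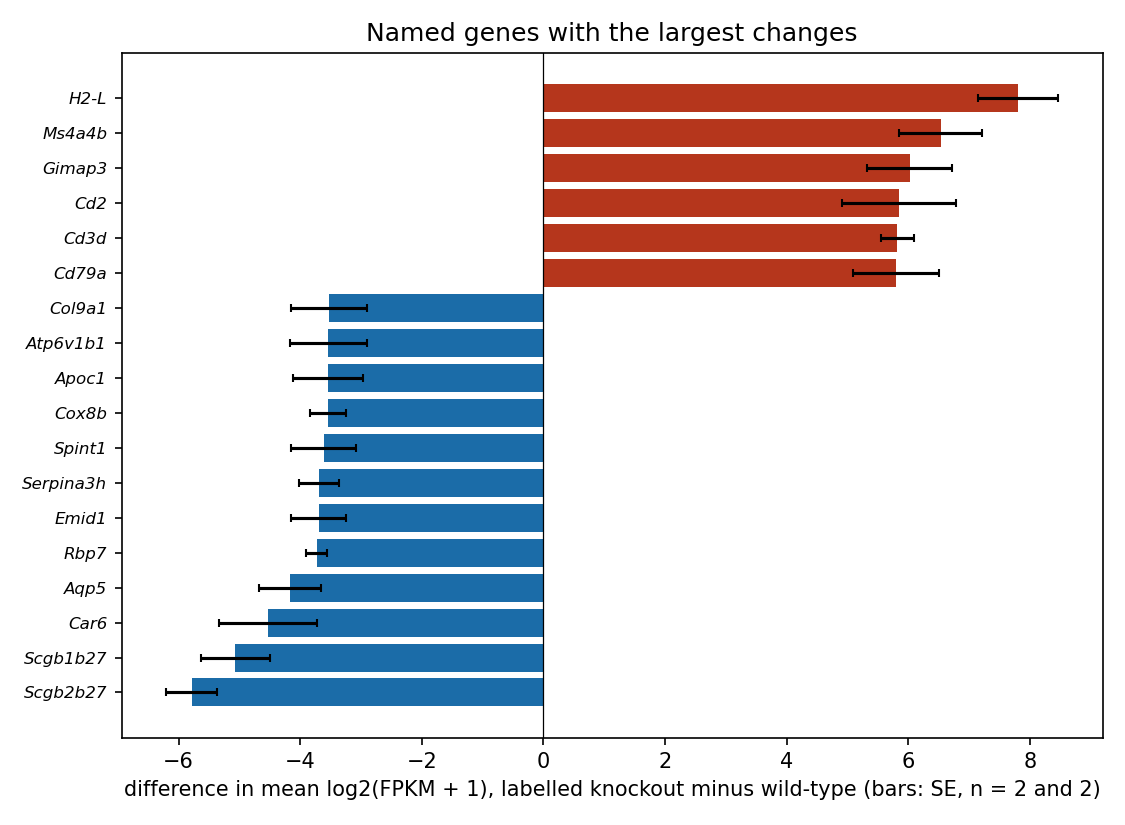
Differences in mean log2(FPKM + 1), labelled knockout minus wild-type, for named genes with large changes past the threshold; each bar is 1 gene and the whiskers are the standard error of the fit (2 libraries per group). The 4 small RNA rows listed at 0 in both wild-type libraries are left out. Lymphocyte genes such as Cd2, Cd3d and Cd79a lie near 6 and the secretoglobin Scgb2b27 lies at -5.78.

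Markers of blood cells were examined next, since a sort of tumor cells can carry other cells. In the lymphocyte list 15 of 16 measured genes rose, none fell and 1 did not pass (16 rose when adjusted over the list alone), with a median change of 5.07. Besides Cd79a and Cd3d, the B cell gene Ms4a1 was at 1.41 and 1.38 FPKM in wild-type and at 54.9 and 47.7 FPKM in the libraries labelled knockout, and the NK cell receptor Klrd1 went from 0.515 and 0.346 to 38.4 and 37.5 FPKM. The list passed the test against all other genes (camera with a preset correlation of 0.01, adjusted p = 5.39e-09), but not with an estimated correlation (adjusted p = 0.70 with an estimated correlation); fry gave an adjusted p of 0.035. In the neutrophil list 3 of 9 genes rose and 6 did not pass (5 rose when adjusted over the list alone). The granule genes Ngp and Camp rose by 3.93 (SE 0.35) and 3.69 (SE 0.56) and the collagenase Mmp8 by 1.80 (SE 0.21), while S100a8 was at 199 and 318 FPKM in wild-type and at 615 and 643 FPKM in the libraries labelled knockout (adjusted p = 0.052). The neutrophil list had a camera adjusted p of 0.0092 (adjusted p = 0.70 with an estimated correlation), and its median change of 2.05 was 1.06 without the first wild-type library.

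The macrophage and dendritic cell list did not separate the groups. None of its 19 genes passed, the median change was -0.58, and the camera adjusted p was 0.60 (adjusted p = 0.90 with an estimated correlation). The second wild-type library stood apart: the complement genes C1qa and C1qc were at 40.5 and 39.9 FPKM in the first wild-type library, 1254 and 1154 FPKM in the second, and between 34.3 and 46.4 FPKM in the libraries labelled knockout. Ptprc, the pan-leukocyte antigen CD45, was at 2.73 and 32.2 FPKM in wild-type and at 112 and 111 FPKM in the libraries labelled knockout (adjusted p = 0.12), and Laptm5, a lysosomal protein of blood cells, was at 8.82 and 169 against 208 and 175 FPKM. Without the second wild-type library the macrophage list had a median change of 1.81, and without the first of -2.40.

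Epithelial gene lists had negative median changes in the libraries labelled knockout, although few single genes passed. Of 23 epithelial junction genes 2 fell, none rose and 21 did not pass (11 fell when adjusted over the list alone), with all 23 lower and a median change of -2.07. The claudin Cldn3 fell from 288 and 115 FPKM to 15.5 and 19.9 FPKM, and the tight junction scaffold Tjp1 from 2.44 and 1.49 to 0.217 and 0.354 FPKM. Cldn4 was at 427 and 111 FPKM against 21.3 and 17.4 FPKM (adjusted p = 0.053), and the serine protease Prss8 at 26.0 and 8.10 against 1.89 and 1.17 FPKM (adjusted p = 0.063). Of the 6 luminal keratin genes none passed over all genes and 5 fell when adjusted over the list alone, with a median change of -2.81. Krt18 was at 4312 and 949 FPKM in wild-type and at 254 and 261 FPKM in the libraries labelled knockout, Krt19 at 517 and 97.6 against 27.5 and 33.1 FPKM, and Krt23 at 7.62 and 5.40 against 2.23 and 1.57 FPKM. Of 10 luminal progenitor genes 1 fell and 9 did not pass (4 fell when adjusted over the list alone). The Notch target Hey1 changed by -2.15 (SE 0.28), and the transcription factor genes Elf5 (-2.40, SE 0.49; adjusted p = 0.051), Ehf (-2.28, SE 0.48; adjusted p = 0.054) and Sox10 (-2.77, SE 0.68; adjusted p = 0.068) did not pass. Of 8 basal genes, Acta2, smooth muscle actin (-1.45, SE 0.25), and Igfbp5 (-2.59, SE 0.46) fell and 6 did not pass (2 fell when adjusted over the list alone); Tagln changed by -0.91 (adjusted p = 0.093) and Cnn1 by -1.05 (adjusted p = 0.12).

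The camera adjusted p was 4.27e-06 for the junction list, 0.021 for the keratins, 0.011 for the luminal progenitor list and 0.0098 for the basal list (adjusted p = 0.70 with an estimated correlation in each). Without the first wild-type library the median change was -1.18 for the junction list, -1.59 for the keratins and -0.95 for the basal list, against -1.43 for the basal list with all libraries. In the same libraries labelled knockout the lymphocyte list median was 6.78 and 6.67 on the log2(FPKM + 1) scale, against 0.97 and 2.27 in wild-type.

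Milk genes moved in both directions. Of 15 measured genes 4 fell, 1 rose and 10 did not pass (7 fell and 2 rose when adjusted over the list alone). The osteopontin gene Spp1 fell by 1.64 (SE 0.17), Lalba, the alpha-lactalbumin gene, by 2.65 (SE 0.31) and the milk fat globule enzyme Xdh by 2.05 (SE 0.27), whereas the beta-casein gene Csn2 rose from 14.2 and 24.9 FPKM to 118 and 85.6 FPKM. The list had a median change of -1.28 and a camera adjusted p of 0.035 (adjusted p = 0.70 with an estimated correlation), but it did not pass after median centring (0.067), after quantile normalization (0.064), with a filter at 5 FPKM (0.16), without the first wild-type library (0.091) or without the second library labelled knockout (0.066). The median was -0.83 without the first wild-type library and -2.03 without the second. The lymphocyte list was higher in the same libraries.

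Stromal markers were lower in the libraries labelled knockout as lists, with no gene past the threshold. Of 9 endothelial genes 8 were lower, with a median change of -2.41 (camera adjusted p = 0.026; adjusted p = 0.70 with an estimated correlation). Emcn, an endothelial sialomucin, was at 19.8 and 100.04 FPKM in wild-type and at 2.92 and 3.34 FPKM in the libraries labelled knockout (adjusted p = 0.066), Kdr at 1.97 and 8.37 against 0.406 and 0.384 FPKM, and Flt1 at 1.53 and 5.41 against 0.509 and 0.44 FPKM. Of 15 fibroblast genes 14 were lower, with a median change of -0.75 (camera adjusted p = 0.035; adjusted p = 0.82 with an estimated correlation). Postn was at 81.1 and 157 FPKM against 46.4 and 49.2 FPKM, Lum at 16.5 and 42.7 against 8.54 and 9.39 FPKM, and Thy1, which T cells also express, at 0.519 and 1.94 against 8.25 and 6.13 FPKM. Both calls ended without the second wild-type library, where the median was -0.79 for endothelial (adjusted p = 0.068) and -0.16 for fibroblast genes (adjusted p = 0.38). Without the first the medians were -3.94 and -1.54, and the endothelial call also ended with a filter at 5 FPKM (adjusted p = 0.21). The lymphocyte list was higher in the same libraries.

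**Figure D3:**
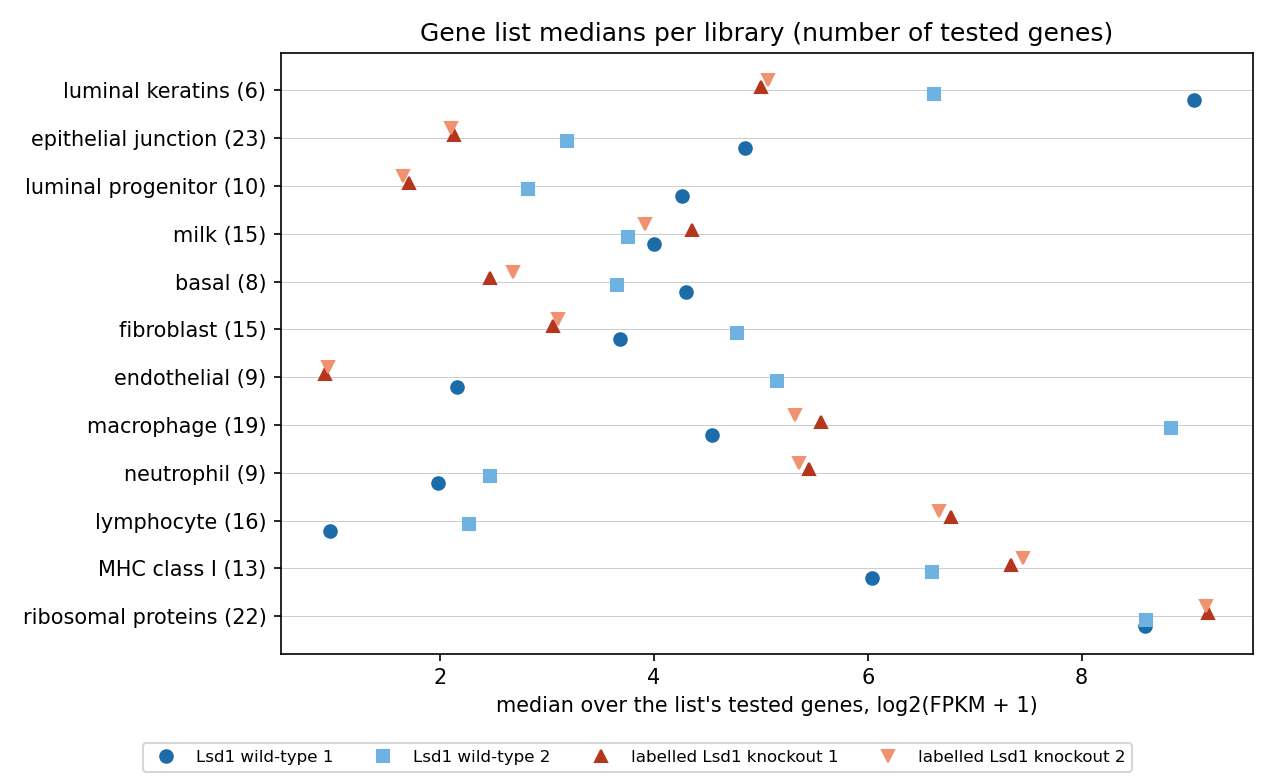
Median log2(FPKM + 1) over the tested genes of 12 gene lists, with 1 point per library; the number of tested genes is in parentheses. The lymphocyte medians are 0.97 and 2.27 in wild-type and 6.78 and 6.67 in the libraries labelled knockout, the luminal keratin medians run the other way, and the macrophage median is highest in the second wild-type library (8.84). The milk medians do not follow the list's median change, because its genes move in both directions.

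The ribosomal protein and class I antigen presentation lists had positive median changes in the libraries labelled knockout. Of 22 ribosomal protein genes 12 rose, none fell and 10 did not pass (18 rose when adjusted over the list alone), with a median change of 0.81. Rpl13 went from 922 and 969 FPKM to 2094 and 2142 FPKM, Rpl32 rose by 0.94 (SE 0.11), Rps24 by 1.14 (SE 0.14) and Rps18 by 0.94 (SE 0.12). Ribosomal protein genes have many processed pseudogenes, so reads can be split between copies. Of 13 class I genes 4 rose and 9 did not pass (6 rose when adjusted over the list alone). Nlrc5, a transactivator of class I genes, rose by 1.42 (SE 0.23), H2-K1 by 0.92 (SE 0.15), the immunoproteasome subunit Psmb8 by 0.97 (SE 0.16) and H2-T23 by 1.13 (SE 0.22); the H2 genes share reads with near copies. The camera adjusted p was 2.92e-05 for the ribosomal and 0.0092 for the class I list (adjusted p = 0.70 with an estimated correlation in each). The class I median change of 0.91 was 0.56 without the first wild-type library. Both lists were higher in the libraries where the lymphocyte list was higher.

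The matrix protease and mitosis lists had negative median changes, of -0.94 and -0.71, with 2 and 3 members higher. Of 18 protease and matrix genes 5 fell and 13 did not pass (8 fell when adjusted over the list alone). The lysosomal proteases Ctsl (-2.20, SE 0.17) and Ctsb (-2.52, SE 0.47), the inhibitor Timp2 (-2.20, SE 0.38) and the urokinase receptor Plaur (-0.90, SE 0.16) fell, as did Adamts1 (-1.11, SE 0.22). Ctsb and Ctsl are also abundant in macrophages. Ctsb was higher in the second wild-type library (317 and 755 FPKM), where the macrophage list was highest, but Ctsl was not (224 and 196 FPKM). Of 17 mitosis genes Ube2c (-1.61, SE 0.21), Birc5, the survivin gene (-1.49, SE 0.20), and Hmmr (-1.11, SE 0.19) fell and 14 did not pass (3 fell when adjusted over the list alone); the checkpoint kinase gene Bub1b changed by -0.84 (adjusted p = 0.084). The camera adjusted p was 0.0018 for the proteases and 0.0071 for mitosis (adjusted p = 0.70 with an estimated correlation in each), and the mitosis call ended without the second wild-type library (median change -0.43 in place of -0.71, adjusted p = 0.13). Of 24 oxidative phosphorylation genes Uqcrb (-0.95, SE 0.14) and Ndufa4 (-0.77, SE 0.15) fell and 22 did not pass, with 0 passing over the list alone. Atp5j changed by -0.62 (adjusted p = 0.056) and Ndufb8 by -0.69 (adjusted p = 0.056). The list's camera adjusted p was 0.031 (adjusted p = 0.70 with an estimated correlation), and it was 0.069 after quantile normalization and 0.093 when each library was rescaled to a common total. It also did not pass without any one of the 4 libraries (adjusted p = 0.053 and 0.081 without the first and second wild-type library, 0.10 and 0.076 without the first and second labelled knockout). The lymphocyte markers rose in the libraries where these lists were lower.

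Genes tied in the literature to luminal identity or to invasion were compared whether or not they passed. Gata3, a luminal transcription factor that T cells also express, was at 18.8 and 4.48 FPKM in wild-type and at 11.3 and 9.45 FPKM in the libraries labelled knockout (adjusted p = 0.91). Trim37, a ubiquitin ligase gene, was at 2.85 and 1.64 against 1.53 and 1.21 FPKM (adjusted p = 0.32). Cdh1, the E-cadherin gene, was at 126 and 20.2 against 7.98 and 9.68 FPKM (adjusted p = 0.15), and Vim at 39.8 and 279.7 against 107.6 and 103.7 FPKM (adjusted p = 0.997). Krt8, whose promoter drove Cre, was at 4653 and 929 against 255 and 259 FPKM (adjusted p = 0.084), and Krt14 at 289 and 83.3 against 48.4 and 50.5 FPKM (adjusted p = 0.16). Esr1, the estrogen receptor gene, stayed under 0.5 FPKM in every library, the highest value being 0.476 FPKM, and was not tested. None of these tested genes passed the threshold with all 4 libraries, and their changes depended on which wild-type library was used. With 1 wild-type library left, the fit holds no spread between wild-type libraries, so only the changes are given. Without the first and without the second, Gata3 changed by 1.05 and -0.80, Vim by -1.40 and 1.39, Cdh1 by -1.12 and -3.69, Krt8 by -1.85 and -4.17 and Krt14 by -0.74 and -2.53. Trim37 changed by -0.70 without the second. Without the first, its remaining wild-type value of 1.64 FPKM lay close to the 1.53 and 1.21 FPKM of the libraries labelled knockout.

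The mesenchymal list did not separate the groups (median change -0.06, camera adjusted p = 0.45). Of its 12 genes Zeb1, which T cells also express, rose (2.51, SE 0.36), Snai1 fell (-0.82, SE 0.16) and 10 did not pass (1 rose and 2 fell when adjusted over the list alone). Snai2 was at 7.05 and 4.29 FPKM against 1.34 and 0.623 FPKM (adjusted p = 0.051) and Sparc at 180 and 764 against 79.2 and 82.9 FPKM (adjusted p = 0.12). In the hormone-sensing luminal list (camera adjusted p = 0.30) Spdef (-2.15, SE 0.18) and the prolactin receptor gene Prlr (-1.83, SE 0.27) fell, Tnfsf11, the RANK ligand gene, which T cells also express, rose (2.41, SE 0.22) and 5 of 8 did not pass (2 fell and 1 rose when adjusted over the list alone). Among LSD1 and its partners (camera adjusted p = 0.42) Gfi1, a repressor of blood cells that recruits LSD1, rose from 0.0618 and 0 FPKM to 3.71 and 3.98 FPKM and 13 of 14 did not pass (1 rose when adjusted over the list alone), Hdac1 being at 41.0 and 38.1 against 70.2 and 71.5 FPKM (adjusted p = 0.051). Among other histone demethylases (camera adjusted p = 0.071) Kdm3a (1.83, SE 0.22) and Kdm2b (1.43, SE 0.28) rose and 15 of 17 did not pass (1 rose when adjusted over the list alone); with no filter on low values this list was called higher (adjusted p = 0.015).

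The fry test passed the LSD1 list upward (adjusted p = 0.035), the Wnt and Notch list upward and the immediate early list downward (adjusted p = 0.031 each), none of which passed camera. Of the lists that passed camera, fry also passed the lymphocyte, ribosomal protein, neutrophil and oxidative phosphorylation lists, and gave adjusted p-values of 0.082 to 0.50 for the others, with 0.23 for the junction and the keratin list. The remaining lists did not pass the camera test. In the Wnt and Notch list (adjusted p = 0.76) the T cell transcription factors Lef1 (5.14, SE 0.26) and Tcf7 (4.34, SE 0.28) rose with Znrf3 (1.77, SE 0.18), and Hes1 fell (-1.73, SE 0.18), with 6 of 10 not past the threshold (3 rose and 1 fell when adjusted over the list alone); its median change was -0.13 while its mean was 0.80 and the test pointed up. Of the immediate early genes (adjusted p = 0.15) Atf3 (-2.14, SE 0.17), Jun (-1.79, SE 0.16) and Fos (-1.41, SE 0.28) fell and 14 of 17 did not pass (3 fell when adjusted over the list alone). Of the DNA replication genes (adjusted p = 0.34) Mcm4 (2.08, SE 0.33), Mcm6 (1.10, SE 0.20) and Cdt1 (3.99 and 7.12 FPKM against 18.4 and 21.1 FPKM) rose and 16 of 19 did not pass (3 rose when adjusted over the list alone). Of the TGF-beta genes (adjusted p = 0.22) Tgfb3 (-1.67, SE 0.27) and Cyr61 (-2.56, SE 0.46) fell, Smad7 rose (1.16, SE 0.22) and 12 of 15 did not pass (1 rose and 3 fell when adjusted over the list alone). In the hypoxia and glycolysis list (adjusted p = 0.48) P4ha1 (2.42, SE 0.25) and Pdk1 (1.80, SE 0.34) rose and Car9 fell (-1.93, SE 0.34), with 17 of 20 not past the threshold (2 rose and 1 fell when adjusted over the list alone). Among interferon genes (adjusted p = 0.14) Oasl1 fell (-1.91, SE 0.23) and 23 of 24 did not pass (1 fell when adjusted over the list alone). Among inflammatory genes (adjusted p = 0.49) Ccl5, a chemokine of T cells, rose (2.09, SE 0.26; 1 rose when adjusted over the list alone), and among cholesterol genes (adjusted p = 0.58) Stard4 rose (1.24, SE 0.23; 0 when adjusted over the list alone). No gene passed in the unfolded protein response (adjusted p = 0.30), p53 target (adjusted p = 0.67), adipocyte (adjusted p = 0.16), erythroid (adjusted p = 0.15) or skeletal muscle (adjusted p = 0.58) lists; adjusted over the list alone, 1 erythroid gene fell and 0 passed in the others. Lists newly called without the first wild-type library included the histone demethylase, adipocyte, erythroid, mesenchymal and muscle lists. Without the second, the interferon and unfolded protein response lists were newly called. These fits hold no spread between wild-type libraries.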

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

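Rescaling each library to a common total, leaving out small RNA rows and averaging the pair labelled knockout were chosen after seeing the data. The count of changed genes depended most on which libraries set the spread. Over the settings that each left out 1 library, it ran from 0 to 7912 (0 to 4269 higher and 0 to 3643 lower). The lone library left in a group is there assumed to vary like the other group, so the loss of all calls without either library labelled knockout follows from the spread then being that of the wild-type pair alone, and the rise without either wild-type library from its being that of the pair labelled knockout. Averaging the pair labelled knockout into 1 sample gave 0 genes changed, 0 higher and 0 lower (limma, 1375 at an unadjusted p under 0.05). With no filter on low values 2 genes changed, 2 higher and 0 lower, among 17257 tested; the cause was not tested. At an adjusted p of 0.1, 3719 genes changed. The replicate numbers do not pair the libraries by any label, and same-numbered libraries did not deviate together (correlation across genes -0.06). With the replicate block 501 genes changed, 346 higher and 155 lower, of which 494 were among the 1837; the fit has 1 residual degree of freedom fewer. The split of the first against the second libraries of each group called 0 genes, and the remaining split called 3. Kdm1a ran from -1.25 to -0.0866 over the settings that each left out 1 library. Ordinary limma, median centring, quantile normalization, the filter at 5 FPKM, a pseudocount of 0.1, rescaling and leaving out small RNA rows gave 1458 to 1891 changed genes. The split of higher and lower genes moved with scaling, from 1059 and 778 to 884 and 848 with median centring and 963 and 545 when rescaled. The gene lists changed numbered 12 to 18 without each library in turn, 0 with an estimated correlation and 7 with fry; other settings gave 12 to 15. The oxidative phosphorylation list did not pass with the replicate block (camera adjusted p = 0.078) or with the pair averaged (0.090), and the block ended no other list's call. Without each library in turn, Vim ran from -1.40 to 1.39, Gata3 from -0.80 to 1.05, and the list medians from -2.40 to 1.81 for macrophage, -1.08 to 0.91 for mesenchymal, -2.39 to 0.33 for muscle, -0.40 to 0.11 for cholesterol, -0.91 to 0.0751 for unfolded protein response, -0.48 to -0.052 for hypoxia and glycolysis, 0.18 to 0.84 for inflammatory and 0.0597 to 0.42 for p53 target genes, with the direction of each list's test reversed in at least 1 of them. Vim was 0.0166 with quantile normalization, 6e-04 with a pseudocount of 0.1 and 0.079 when rescaled, and the hypoxia list, at a median of -0.21, was tested upward by fry; the cause was not tested. DESeq2, limma-voom and size factors, planned in case the file held counts, were not run on FPKM. Depth limits genes near 0.1 FPKM, where values stood at a few reads; intervals were not computed because the counts themselves are not known.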

Other observations

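The tests of the explanations weighed here, and Trf, Lcn2, Hspb1, Apoe, Lyz2, Cd74, Foxp3, Xist, Tsix and Firre, were chosen after the values were seen. The lymphocyte transcripts in the libraries labelled knockout covered several lineages. Cd8a rose from 0.207 and 1.40 FPKM to 43.7 and 40.1 FPKM, and Foxp3, the transcription factor of regulatory T cells, from 0.206 and 0.824 FPKM to 8.29 and 7.05 FPKM, while Cd4 was at 1.78 and 10.3 against 27.3 and 21.4 FPKM (limma, adjusted p = 0.12). The wild-type libraries differed from each other in another way. The second held the macrophage and antigen presentation transcripts Apoe (15205 FPKM, against 543 in the first), Lyz2 (9165 against 238 FPKM) and Cd74 (10256 against 431 FPKM). The first held more of the epithelial secretory transcripts Trf (6009 against 1144 FPKM) and Lcn2 (5899 against 1166 FPKM) and of the heat shock gene Hspb1 (7419 against 1304 FPKM). These are values of single libraries with no test.

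The X-inactivation transcript Xist was at 3.31 and 3.93 FPKM in the wild-type libraries and at 0 and 0.0096 FPKM in the libraries labelled knockout (log2 change -2.20, SE 0.18; limma, adjusted p = 0.024). Tsix, which overlaps it on the other strand, was at 5.99 and 9.28 against 0.0204 and 0.0283 FPKM, and the X-linked noncoding RNA Firre at 6.67 and 3.50 against 0.728 and 0.787 FPKM (adjusted p = 0.048). Without stated strand use, Xist and Tsix reads cannot be told apart.

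The first pattern is the rise of lymphocyte transcripts. The presence of T and B cells in the sorted fraction stays open: in a second set of lineage genes outside the lymphocyte list, 14 of 14 T cell genes and 11 of 11 B cell genes were higher, with median changes of 4.51 and 3.77, but these measure the same signal again and do not place it in a cell. Lat and Cd27 reached 164 and 118 FPKM in the first library labelled knockout, although a sort on the reporter was meant to remove cells that never met Cre. A lower share of epithelial cells that raised every other cell type alike is argued against, since the lowest lymphocyte change between any wild-type library and any labelled knockout (4.40) exceeded the highest fibroblast or endothelial change (-0.58) by 4.98. Whether loss of LSD1 changed the tumor cells themselves stays open: the luminal keratins had a median change of -2.81 in the same libraries, and bulk values do not place a transcript in a cell.

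The second pattern is the near absence of Xist. Dilution of Xist-expressing epithelial cells is argued against: scaled by Krt8, Krt18 or Epcam, the lowest predicted level was 0.181 FPKM, 18.8 times the highest observed one. Male cells in a sample labelled female stay open, because 37 rows of Y chromosome genes (GRCm38 RefSeq) were at 0 in all 4 libraries and it is not known whether Y reads could be assigned. Loss of 1 X chromosome also stays open: the median change of 309 X-linked genes differed from that of 10157 autosomal genes by -0.01, as it may if the silent X were lost or if none were. A loss confined to tumor cells would not remove Xist RNA of other female cells, and lymphocyte transcripts were high in the same libraries. Which cells those transcripts came from is not known, so they do not decide the question. An effect of LSD1 loss on Xist itself was not tested.

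The third pattern is Kdm1a RNA in the libraries labelled knockout at the level of the second wild-type library. RNA from cells that did not undergo Cre recombination stays open, although the sort on the reporter was meant to remove them. The lymphocyte list was higher in the same libraries, and bulk values do not say which cells gave the Kdm1a RNA. The Kdm1a change lay above the median keratin change by at least 1.45 on the log2 scale in all 4 library pairs. However, 55.5% of tested genes did so by as much. A deletion that leaves most of the transcript could also give the mean of 21.5 FPKM, and the file holds 1 value per gene, so it stays open. Intact Lsd1 in the samples titled knockout stays open as well: the tissue label of 2 samples titled knockout reads Lsd1+/+, against their genotype label.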
